A study of Saccharomyces cerevisiae with 30 samples.

How the data were processed

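Histone H3 exchange was measured in 5 yeast strains (WT, isw1, chd1, isw1 chd1, ioc4) by chromatin IP of FLAG-tagged and of Myc-tagged H3, with 3 biological replicates per IP and strain, on 30 Agilent two-colour tiling arrays. Per the labels, cells were grown in YPD to OD 0.4, held in alpha factor (2 uM) for 5 h and crosslinked. IPs used 15 ul of FLAG or 2 ul of Myc antibody, the DNA was amplified linearly with T7 polymerase, and amino-allyl RNA was coupled to dye. Groups and dyes (Cy5 for IP, Cy3 for input) were taken from the labels, and each file from its sample record.

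The deposited array files hold processed signals in intensity units; per the file headers they were made with Feature Extraction 10.5.1.1 on a design annotated on sacCer1, with spatial and multiplicative detrending and a linear dye normalization. The deposited series matrix holds log2 values of IP over input on which each array had been rescaled: the slope on the log2 ratio of the array files was 0.56 to 0.82 for FLAG and 1.25 to 1.95 for Myc arrays, with r of 0.936 to 0.998 across probes. R 2.13.0 is named in the submitters' processing notes, without the steps. Columns of other units in the deposited files, such as flags and positions, were used as such. Because the series matrix brings FLAG and Myc arrays to a similar spread, the processed signals were used, and the series matrix served as an alternative.

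The log2 ratio of Cy5 to Cy3 processed signal was computed for 60647 probes per array, and the median over non-control probes was set to 0 on each array. Spots marked as outliers by the scanner software (3 to 4986 per array) were left out. No reference genome came with the data, so each probe was given to the gene that the array file names for it: 55593 probes name 1 gene, and 4565 name both genes of a divergent promoter. Of 5635 gene names, 5629 matched a current gene table, which gave locus tags and neighbours. A gene therefore means the span of the probes that carry its name (median 9 probes, 1465 bp, with a spacing of 181 bp), which can hold some flanking sequence, and a promoter means the probes of a divergent pair. This departs from the plan of open reading frame boundaries and a promoter of fixed length. For the same reason the alternatives with probes inside 1 open reading frame only and with a shorter promoter were not run. Probe signals were averaged per gene, promoter and each of 3 equal parts of the named span.

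Gene values were fitted with limma 3.58.1 in R 4.3.3 (files read with data.table, version 1.17.8), with 10 group means over 30 arrays, eBayes and Benjamini-Hochberg adjustment at 0.05. Contrasts were FLAG minus Myc in a mutant minus the same in WT, each tag alone, isw1 chd1 minus both single changes, isw1 minus ioc4 and isw1 minus chd1. Genes needed 2 or more probes. ISW1, CHD1 and IOC4 were left out, as were CUP1-1 and YLR157W-E, whose input was more than 2 log2 units from WT in a mutant, which left 5485 genes. The last part alone, with 3874 genes of 1000 bp or more, was fitted after the profile had been seen. The 3′ shift was the mean over 1631 genes of the last part minus the promoter; exact two-sided permutation tests moved strain labels within FLAG and within Myc arrays (400 arrangements) and with FLAG and Myc of 1 replicate number together (20 arrangements). The test of the double mutant's shift against the sum of the single shifts used 100000 permutations.

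Gene lists were tested with camera at an inter-gene correlation of 0.01 and with an estimated one, and with fry. The 20 lists were ribosomal protein, ribosome biogenesis, glycolysis and fermentation, pheromone response, galactose utilisation, histone, G1/S and S phase, M and M/G1 phase, heat shock and stress, amino acid biosynthesis, proteasome, respiratory chain and ATP synthase, sporulation and meiosis, and cryptic initiation reporter genes, Y prime helicases, 4 classes of named span (under 1000 bp, 1000 bp to under 2000 bp, 2000 bp to under 3000 bp, 3000 bp and over) and genes within 20 kb of a chromosome end. Distance to a chromosome end was taken from the outermost probe of the chromosome, so such genes can lie farther from the end itself. Y prime helicases had 0 measured members, so 19 lists and 4 mutants made 76 tests. A list of Ty elements could not be matched to probes. A list of glucose-repressed carbon metabolism genes was added after the ioc4 values had been seen.

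Named genes were chosen by a rule set before the data were examined: in each mutant, among genes past the threshold with changes of 1 direction on both sides of the middle probe, the 10 largest rises and the 10 largest falls; STE11, FLO8, SPB4 and PCA1 in every mutant; the members with the smallest p in each list described; and the 3 with the smallest p in each direction for contrasts between mutants. Tests and the alternatives listed first below were also set before the data were examined. They were normexp background correction with an offset of 50, loess within arrays, MAD scaling over all arrays, quantile normalization within FLAG and within Myc, probes well above background, outlier spots kept, the series matrix, 1 or 4 probes as the minimum, the median of probes, replicate number as a block over all arrays or within strains, only the compared strains, trend and robust eBayes, the slide as a random block, named spans of 2000 bp or more, the first part as reference, and leaving out each array. Alternatives added after seeing the data were scan batches 1 and 2 alone, the slide date as a fixed block, MAD scaling within FLAG and within Myc, removal of a spline trend (4 degrees of freedom) on probe GC content with and without the replicate block, and genes with a convergent downstream neighbour.

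Scan dates made 5 batches. Batch 1 held WT and isw1 (2 replicates of each IP), batch 2 the remaining replicate of both with 2 chd1 replicates, batch 3 a chd1 Myc array, batch 4 a chd1 FLAG array with isw1 chd1, and batch 5 ioc4. Replicate numbers paired FLAG and Myc within strains: log ratios of such pairs correlated in 15 of 15 cases after group means were removed (0.159 to 0.62), as did their inputs (0.66 to 0.933). Numbers did not pair arrays across strains (9 of 60 pairs above 0.1). On simulated data with 5481 genes, the isw1 fit recovered 41 of 100 changes of 0.5 log2 units and 93 of 100 changes of 1 log2 unit, with 4 false calls, and made 0 calls in an unchanged comparison. The simulated noise was independent between arrays, without pair or batch effects, so these rates need not hold for the real arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.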

Results

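Histone H3 exchange was mapped on tiling arrays in 5 budding yeast strains: wild type (WT) and strains lacking ISW1, CHD1, both genes (isw1 chd1) or IOC4. Isw1 and Chd1 are ATP-dependent chromatin remodelers, and Ioc4 is a subunit of the Isw1b form of the Isw1 complex. Each strain carried a FLAG-tagged and a Myc-tagged histone H3, and each tag was immunoprecipitated (IP) in 3 biological replicates, which gave 10 groups and 30 arrays. Cells were arrested with the mating pheromone alpha factor (2 uM, 5 h) before crosslinking. On every array the IP was labelled with Cy5 and the input DNA with Cy3. Exchange was taken as the log2 ratio of IP to input for FLAG minus that for Myc, after the title of the series, which calls the measurement histone exchange; the labels do not say how either tagged H3 was produced. Median input signal per array was 1061 to 1449 intensity units, and 98.5% to 99.7% of probes stood well above background in both channels. Replicate arrays of 1 group correlated across nuclear probes with r of 0.70 to 0.96. FLAG and Myc arrays, paired in every combination, correlated with r of -0.55 to -0.04 across those probes. Probes are not independent replicates.

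The input channel matched the strain labels at the 3 deleted genes. Over the ISW1 probes the centred log2 input signal was -6.39 to -3.33 on the 12 arrays of the strains without ISW1 and 0.11 to 0.39 on the other 18. Over the CHD1 probes it was -8.17 to -4.64 on the 12 arrays of the strains without CHD1 and -0.20 to 0.24 elsewhere. Over the IOC4 probes it was -5.47 to -3.50 on the 6 ioc4 arrays and -0.07 to 0.28 elsewhere. Some of these probes fell to background, so the losses are lower bounds: input was at least 14.2-fold lower than in WT at ISW1 in isw1, at least 54.0-fold lower at CHD1 in chd1 and at least 16.8-fold lower at IOC4 in ioc4.

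**Figure D1:**
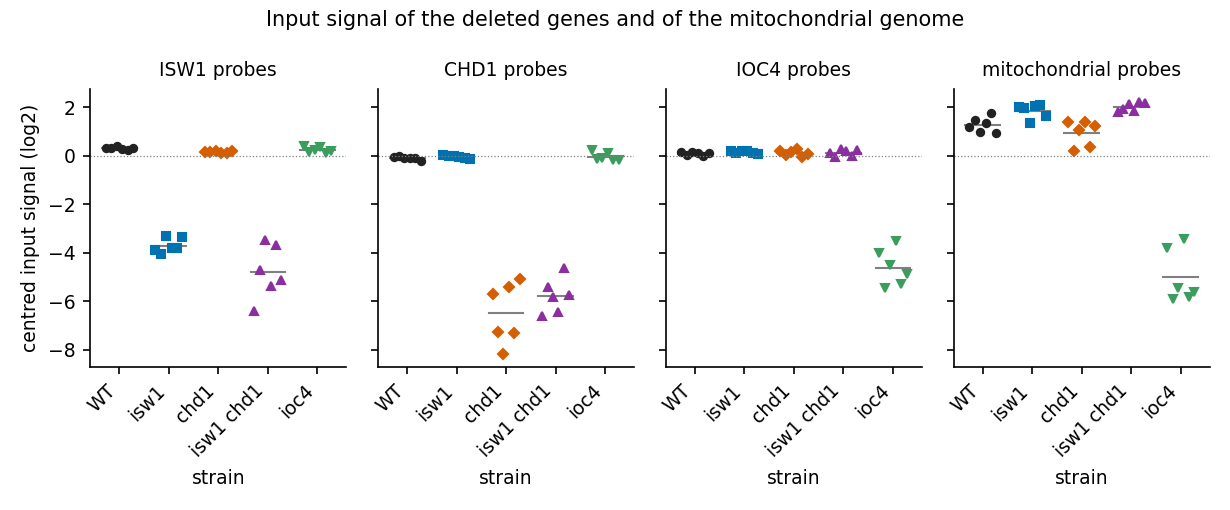
Centred log2 input (Cy3) signal (y axis) over the probes of ISW1, CHD1, IOC4 and the mitochondrial genome (panels) in the 5 strains (x axis), 1 point per array and a bar at the mean. Each deleted gene lay at or below -3.33 in every strain that lacks it, and the mitochondrial probes lay between -5.92 and -3.45 on the 6 ioc4 arrays.

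In WT, exchange was highest at promoters. Over 1631 genes with a promoter shared with a divergent neighbour and a probed span of 1000 bp or more, log2 exchange was 1.34 ± 0.02 (SD, n = 3) at the promoter, -0.04 ± 0.06 in the first of 3 equal parts of the gene, -0.33 ± 0.06 in the middle part and 0.41 ± 0.04 in the last part. The promoter exceeded the gene by 1.32 ± 0.05 (SD, n = 3). In an exact two-sided permutation test over the 3 FLAG and 3 Myc arrays this had p = 0.1, the smallest that 20 arrangements can give. Genes of the mating response had high exchange in WT, such as the agglutinin anchor gene AGA1 (7.41 ± 0.19, SD, n = 3) and the cell wall adhesin gene FIG2 (7.44 ± 0.24, SD, n = 3). The median over the 36 measured pheromone response genes was 3.22.

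The question of where along genes exchange changes without the remodelers was addressed with the same 1631 genes. Array medians were set to 0, so genome-wide gains or losses of exchange cannot be seen here or in the gene counts below. On that scale exchange fell at promoters and rose at 3′ ends in isw1, chd1 and isw1 chd1. At the promoter it was 0.71 ± 0.05 in isw1, 0.36 ± 0.10 in chd1 and -0.28 ± 0.02 in isw1 chd1 (SD, n = 3). In the last part it was 0.57 ± 0.01 in isw1, 1.12 ± 0.05 in chd1 and 1.2 ± 0.05 in isw1 chd1 (SD, n = 3). In chd1 and isw1 chd1 the WT order was turned around, with more exchange in the last part than at the promoter. The ioc4 values were 1.21 ± 0.03 at the promoter and 0.40 ± 0.02 in the last part (SD, n = 3).

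**Figure D2:**
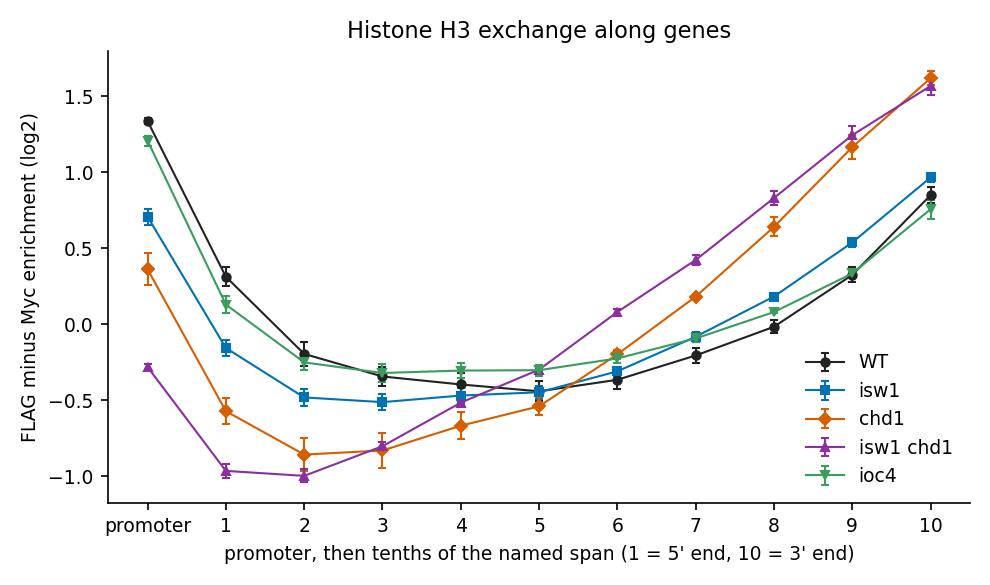
Mean exchange (FLAG minus Myc enrichment, log2, y axis) at the promoter and in 10 equal parts of the probed span from the 5′ to the 3′ end (x axis), over 1631 genes, 1 line per strain with the SD of 3 replicates. The promoter value runs from 1.34 in WT to -0.28 in isw1 chd1, and at the 3′ end isw1 chd1 lies above WT instead.

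The last part minus the promoter measures this shift and does not depend on how an array is centred. It was -0.93 ± 0.03 in WT, -0.13 ± 0.06 in isw1, 0.76 ± 0.14 in chd1, 1.48 ± 0.07 in isw1 chd1 and -0.81 ± 0.01 in ioc4 (SD, n = 3). Relative to WT the shift was 0.80 in isw1 (exact permutation p = 0.01, adjusted p = 0.0133), 1.69 in chd1 (p = 0.005, adjusted p = 0.01), 2.41 in isw1 chd1 (p = 0.005, adjusted p = 0.01) and 0.12 in ioc4 (p = 0.02, adjusted p = 0.02), with 3 of 3 replicates above all WT replicates in each mutant. These two-sided tests permute 400 arrangements of the strain labels within FLAG and within Myc arrays, and the adjustment is over 4 tests. FLAG and Myc arrays with 1 replicate number were correlated within strains, and with such pairs permuted together each of the 4 tests gave p = 0.1, the smallest that 20 arrangements can give. The ioc4 shift lost its call with normexp, loess, both MAD scalings, the series matrix values, the first part as reference and the replicate number as a block over all arrays (0.12, permutation p = 0.0625), and its sign with quantile normalization (-0.02). Within scan batches the shift was 0.84 for isw1 in batch 1, 0.71 for isw1 in batch 2 and 1.75 for chd1 in batch 2. Array batches 4 and 5 hold isw1 chd1 and ioc4 arrays without WT, so no within-batch value against WT exists for these strains. Batch 4 also holds a chd1 FLAG array. Its own last part minus promoter was 0.95, against 1.57 to 1.70 on the isw1 chd1 FLAG arrays.

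By segment, with 16 tests adjusted together, the exact permutation test passed at the promoter in isw1 (change -0.63, adjusted p = 0.04), chd1 (-0.98, adjusted p = 0.01) and isw1 chd1 (-1.62, adjusted p = 0.01). The last part also passed in isw1 (0.17, adjusted p = 0.0356), chd1 (0.71, adjusted p = 0.01) and isw1 chd1 (0.79, adjusted p = 0.01), as did the first part in isw1 (-0.31), chd1 (-0.67) and isw1 chd1 (-0.83), each with adjusted p = 0.01. The middle part passed in isw1 chd1 (0.29, adjusted p = 0.01). The isw1 promoter change was -0.28 with loess (exact permutation p = 0.055), the isw1 last part with named spans of 2000 bp or more had p = 0.05 (0.19), and both had p = 0.0625 with the replicate number as a block over all arrays. With FLAG and Myc permuted as pairs no segment can go below an exact p = 0.1. No ioc4 segment passed, and the promoter came nearest (-0.13, adjusted p = 0.0582). Under alternatives, exact permutation tests gave unadjusted p values under 0.05 for small changes in ioc4: 0.17 in the middle part (p = 0.005) and 0.044 in the last part (p = 0.02) without the GC trend, 0.19 in the middle part (p = 0.01) and 0.099 in the last part (p = 0.005) with spans of 2000 bp or more, -0.18 in the first part with normexp (p = 0.015), and -0.12 in the first part (p = 0.005) and 0.037 in the last part (p = 0.015) with quantile normalization. The middle part did so in isw1 without the GC trend (0.16, permutation p = 0.04) and with quantile normalization (0.14, p = 0.015), and in chd1 with quantile normalization (0.13, p = 0.04). Without rescaling of the arrays the shift came mainly from FLAG, whose own shift was 0.75 in isw1, 1.37 in chd1 and 1.94 in isw1 chd1. That of Myc was -0.05, -0.32 and -0.47. Myc log ratios spanned less (SD 0.58 to 0.75 per array, against 1.11 to 1.49 for FLAG), and this split was not computed with equal spread. Which tag carries more of the shift can therefore depend on the scaling. Gene by gene, among 3874 genes with a probed last part, exchange in that part rose at 775 and fell at 256 in isw1, rose at 1971 and fell at 358 in chd1, rose at 2315 and fell at 576 in isw1 chd1, and rose at 592 and fell at 566 in ioc4 (limma). With loess 37 genes were left in isw1, 1178 in chd1 and 142 in ioc4 (51 up, 91 down), and in isw1 303 were left with normexp, 450 with MAD scaling over all arrays and 475 with the series matrix. The isw1 count was 320 within batch 1 and 0 within batch 2, where 1 array per group was left and 680 genes had an unadjusted p under 0.05 (limma).

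**Figure D3:**
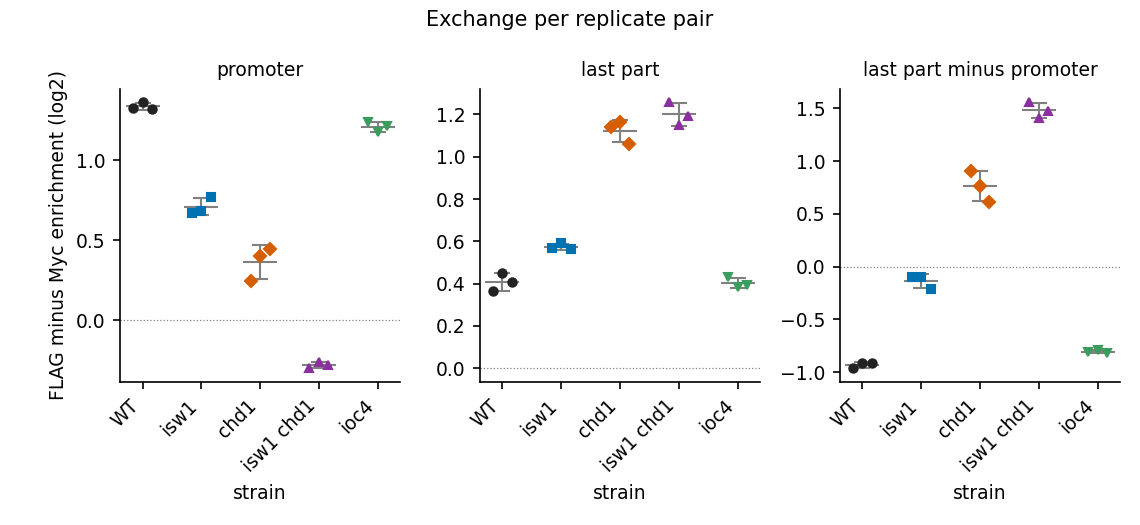
Exchange (FLAG minus Myc enrichment, log2, y axis) at the promoter, in the last part and as last part minus promoter (panels) in the 5 strains (x axis), 1 point per replicate pair with the mean and SD (n = 3). Last part minus promoter lies below 0 in WT, isw1 and ioc4 and above 0 in chd1 and isw1 chd1.

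The isw1 comparison asked which genes change their exchange without Isw1. Of 5485 genes tested, exchange over the whole gene rose at 434 and fell at 1045 in isw1 (limma, adjusted p under 0.05), and 20 rises and 80 falls exceeded 2-fold. The falls included genes with very high exchange in WT: FIG2 went from 7.44 to 5.79 (change -1.66, adjusted p = 1.3e-06) and AGA1 from 7.41 to 6.04 (-1.38, adjusted p = 4.11e-07). The small heat shock protein gene HSP26 (-1.46), the anaphase-promoting complex gene APC9 (-1.49), the iron-sulfur cluster assembly gene ISD11 (-1.40), SNA4 (-1.48), UGX2 (-1.37), YKR041W (-1.44), YGR045C (-1.76) and YNL146W (-1.66) completed the 10 largest falls. The largest rise was at GPX2, a glutathione peroxidase gene on chromosome 2 at 707523 to 707982 (change 2.44 ± 0.25 SE, adjusted p = 2.78e-07). GPX2 lies next to the deleted ISW1, whose probes start at 708159. The other large rises were at TOD6, a repressor of ribosome biogenesis genes (1.51), the splicing factor gene PRP19 (1.50), the actin assembly gene LAS17 (1.39), MGS1 (1.32), the meiotic gene REC104 (1.30), the histidine biosynthesis gene HIS6 (1.24), YML020W (1.21), RRT5 (1.21) and PBR1 (1.19). Each of these 20 changes put 3 of 3 isw1 replicates beyond all WT replicates. Here and in the other mutants these genes were picked from the same arrays as the largest changes past the threshold. Such separation is therefore no added support. With loess none of the 10 falls passed (changes of -0.71 to -0.40, limma), nor did the rises at HIS6 (0.48), LAS17 (1.14) and PBR1 (0.62), and with quantile normalization YKR041W (-0.73) and YNL146W (-1.15) did not pass.

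The direction of the isw1 count followed the scaling: 641 genes rose and 403 fell after quantile normalization within FLAG and within Myc, and 796 rose and 586 fell after removal of a trend on probe GC content. Loess within arrays left 73 genes, and the count was 460 within scan batch 1 and 0 within batch 2, where 1 array per group was left and 970 genes had an unadjusted p under 0.05 (limma). Across all scalings the median change of all genes ranged from -0.13 to 0.01 in isw1, from -0.13 to -0.02 in chd1, from -0.11 to 0.11 in isw1 chd1 and from -0.10 to 0.02 in ioc4. List medians below are therefore set beside the median of all genes, which was -0.12 in isw1, -0.09 in chd1, -0.06 in isw1 chd1 and -0.03 in ioc4.

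Gene lists fixed before the data were examined were tested next. In isw1, exchange fell at 19 of 34 respiratory chain and ATP synthase genes and rose at 0 (median -0.59; camera adjusted p = 3.69e-06), among them ATP1 (-0.89), ATP4 (-0.85) and QCR6 (-1.06). It fell at 20 of 34 proteasome genes and rose at 0 (median -0.53, adjusted p = 8.41e-05), with PRE4 at -0.95 and RPT2 at -0.84. These calls held with an estimated correlation between genes (adjusted p = 0.0238 and 0.00419). Ribosomal protein genes fell at 36 of 133 and rose at 0 (median -0.35, adjusted p = 0.000302), with RPS30A at -1.29 and RPL4B at -0.64, but the adjusted p with an estimated correlation was 0.233. Pheromone response genes fell at 16 of 36 and rose at 0 (median -0.40, adjusted p = 0.000332), including ASG7 (-1.01) and PRM3 (-1.28). With an estimated correlation their adjusted p was 0.32, and their direction relative to all genes was lost with loess and quantile normalization. Galactose utilisation genes fell at 6 of 10 and rose at 0 (median -0.57, adjusted p = 0.00889), including GAL7 (-0.80) and GAL2 (-0.96); the adjusted p was 0.233 with an estimated correlation, the direction turned with loess, and the call was also lost with normexp, both MAD scalings, quantile normalization and the series matrix. Sporulation and meiosis genes rose at 10 of 43 and fell at 3 (median 0.13, adjusted p = 0.00264), including SSP1 (0.71) and DIT1 (0.87), with an adjusted p of 0.144 with an estimated correlation. G1/S and S phase genes rose at 7 of 30 and fell at 3 (median 0.06, adjusted p = 0.0364), with POL12 at 0.61 and the sliding clamp gene POL30 at -1.12; with an estimated correlation the adjusted p was 0.32, and the call was also lost with loess, both MAD scalings and the series matrix. Adjusted over the list alone, 23 respiratory chain, 21 proteasome, 37 ribosomal protein, 19 pheromone response and 7 galactose genes fell, and 10 sporulation and 8 G1/S genes rose.

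The chd1 comparison asked the same of Chd1. In chd1, exchange rose at 1279 genes and fell at 1487 of 5485 (limma), and rises were the larger changes: 401 exceeded 2-fold, against 203 falls. The largest rise was at ATP2, the beta subunit gene of the mitochondrial ATP synthase on chromosome 10 at 647292 to 648660, where exchange went from 1.27 ± 0.19 to 4.73 ± 0.13 (SD, n = 3; change 3.46, adjusted p = 6.79e-17 with limma). Further respiratory genes rose at CYT1 (3.10), ATP5 (2.91), COR1 (2.71) and QCR2 (2.52), together with LSC1 of the citric acid cycle (2.70). ARO9 of aromatic amino acid catabolism (3.00), SFT2 of Golgi transport (2.88), BNA7 of NAD synthesis (2.87) and the pheromone-regulated gene PRM5 (2.52) completed the 10 largest rises. The largest fall was at APP1, a phosphatidate phosphatase gene (-2.88, adjusted p = 5.04e-14). YER138W-A (-2.43), VPS64 (-2.24), LDB16 (-2.18), AGA1 (-2.09), FIG2 (-2.05), BRE2 of the histone H3 methylase complex COMPASS (-1.93), YGL007C-A (-1.93), the pyruvate decarboxylase gene PDC6 (-1.86) and COA4 (-1.85) followed. Each of these 20 changes put 3 of 3 chd1 replicates beyond all WT replicates, but the falls at COA4 (-0.75) and YGL007C-A (-0.81) did not pass with loess.

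As a list, respiratory chain and ATP synthase genes rose at 19 of 34 and fell at 0 in chd1 (median 0.49, adjusted p = 7.13e-08). Ribosomal protein genes rose at 99 of 133 and fell at 6 (median 0.85, adjusted p = 3.64e-17), with RPL28 at 2.51, RPL33B at 1.87 and RPL11B at 1.63. Both calls held with an estimated correlation, each with an adjusted p of 0.00865. Pheromone response genes rose at 24 of 36 and fell at 7 (median 0.89, adjusted p = 1.65e-05): the a-factor transporter gene STE6 (1.80) and the cell fusion gene FUS1 (2.36) rose while AGA1 and FIG2 fell. Heat shock and stress genes rose at 13 of 26 and fell at 4 (median 0.43, adjusted p = 0.0111), with the chaperone genes HSC82 at 1.70 and STI1 at 1.58 and HSP26 at -1.45. Genes within 20 kb of the outermost probe of a chromosome fell at 74 of 208 and rose at 26 (median -0.24, adjusted p = 0.0282), with YOR385W at -1.15 against NDI1 at 2.45. With an estimated correlation the adjusted p of these lists was 0.233 for pheromone response, 0.325 for heat shock and 0.233 for chromosome ends. Alternatives also cost calls: pheromone response with both MAD scalings, heat shock with these, normexp, loess and the series matrix, and chromosome ends with loess, MAD scaling within FLAG and within Myc, the median of probes and the slide date as a fixed block. Adjusted over the list alone, 19 respiratory chain, 99 ribosomal protein, 25 pheromone response and 13 heat shock genes rose, and 73 genes near chromosome ends fell. Within scan batch 2 the chd1 count was 1097 genes, and loess within arrays left 667, of which 438 rose and 229 fell.

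The double mutant was compared with WT for the loss of both remodelers. In isw1 chd1, exchange rose at 1442 genes and fell at 1829 (limma), with 422 rises and 726 falls over 2-fold. The mating genes with very high exchange in WT lost most of it: FIG2, on chromosome 3 at 266880 to 272247, went from 7.44 ± 0.24 to 2.82 ± 0.30 (SD, n = 3; change -4.63, adjusted p = 4.19e-16 with limma), and AGA1 from 7.41 ± 0.19 to 3.29 ± 0.23 (SD, n = 3; -4.13, adjusted p = 1.65e-17 with limma). Large falls were also seen at APP1 (-3.78), YGR045C (-3.36), COA4 (-3.26), YIL014C-A (-3.11), YGR146C-A (-3.10), the proline permease gene PUT4 (-3.09), CBP4 (-3.07) and MIM2 (-3.07). The largest rises were at BNA7 (2.80, adjusted p = 4.23e-12), the ribosomal protein genes RPS1B (2.69), RPL33B (2.68) and RPL8B (2.49), HIS6 (2.60), ATP2 (2.47), the ubiquitin-conjugating enzyme gene CDC34 (2.47), ATP5 (2.45), TAF3 of the transcription factor TFIID (2.39) and COR1 (2.37). Each of these 20 changes put 3 of 3 isw1 chd1 replicates beyond all WT replicates. Falls outnumbered rises with the array medians set to 0, whereas quantile normalization gave 1827 rises and 1468 falls and removal of the GC trend 1972 rises and 1430 falls.

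Ribosomal protein genes rose at 98 of 133 and fell at 10 in isw1 chd1 (median 1.15, adjusted p = 2.65e-17), with RPS22A at 2.35 and RPL13B at 1.67. Proteasome genes rose at 15 of 34 and fell at 4 (median 0.39, adjusted p = 0.0099), with RPN5 at 2.15 and RPN3 at 1.24. Genes within 20 kb of the outermost probe of a chromosome fell at 113 of 208 and rose at 25 (median -0.48, adjusted p = 0.000229), including DLD3 (-1.90), YOR385W (-1.68) and the invertase gene SUC2 (-1.59). These 3 calls held with an estimated correlation (adjusted p = 0.00865, 0.0262 and 0.0408), but that of the proteasome was lost with loess (adjusted p = 0.0754), MAD scaling over all arrays (0.171) and the series matrix (0.119). Ribosome biogenesis genes rose at 15 of 45 and fell at 4 (median 0.22, adjusted p = 0.0197), with NOG2 at 1.08 and NOP1 at 1.66; the adjusted p was 0.32 with an estimated correlation, and the call was also lost with loess and normexp. Pheromone response genes went both ways, with 14 of 36 up and 14 down (adjusted p = 0.867). Adjusted over the list alone, 98 ribosomal protein, 15 proteasome and 15 ribosome biogenesis genes rose and 114 genes near chromosome ends fell.

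The ioc4 comparison asked which genes depend on the Isw1b subunit. Exchange in ioc4 rose at 765 genes and fell at 1138 (limma), and the large changes were falls: 306 exceeded 2-fold, against 38 rises. The largest was at ALD6, the cytosolic acetaldehyde dehydrogenase gene on chromosome 16 at 431429 to 433905, which went from 7.22 ± 0.28 to 2.32 ± 0.16 (SD, n = 3; change -4.89, adjusted p = 3.13e-16 with limma). Other genes of ethanol and acetate use fell as well, at ADH2 (-3.54), ALD4 (-2.91) and the acetyl-CoA synthetase gene ACS1 (-2.91). The pentose phosphate enzyme gene GND1 (-2.93), the NAD kinase gene YEF1 (-3.08), the reductase gene YJR096W (-3.36), YHR138C (-2.83), YJR149W (-2.80) and the cell wall gene KNH1 (-2.80) completed the 10 largest falls. The largest rises were at SPL2, a phosphate starvation gene (2.20, adjusted p = 8.31e-08), LOH1 (2.15), the sphingolipid gene LCB3 (1.59), the meiotic gene MND1 (1.56), PFA3 (1.46), SIP18 (1.45), MAN2 (1.43), YNR068C (1.38), GLO3 (1.33) and SRL2 (1.32). Each of these 20 changes put 3 of 3 ioc4 replicates beyond all WT replicates, but the rise at GLO3 did not pass with loess (0.57).

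Pheromone response genes fell at 31 of 36 and rose at 0 in ioc4 (median -0.92, adjusted p = 2.23e-14), including the kinase gene FUS3 (-2.09), AGA1 (-1.80) and FIG2 (-1.90). Ribosomal protein genes fell at 80 of 133 and rose at 0 (median -0.55, adjusted p = 7.39e-11), with RPL43B at -2.03 and RPS31 at -1.93. Respiratory chain and ATP synthase genes fell at 23 of 34 and rose at 1 (median -0.78, adjusted p = 7.13e-08), with ATP1 at -1.44 and ATP2 at -1.24. These calls held with an estimated correlation (adjusted p = 0.0304, 0.03 and 0.00865). Other lists passed only with the preset correlation. Glycolysis and fermentation genes fell at 9 of 21 and rose at 1 (median -0.34, adjusted p = 0.00302), with PDC6 at -1.82 and PDC1 at -0.92. Galactose utilisation genes fell at 6 of 10 and rose at 0 (median -0.65, adjusted p = 0.00171), with GCY1 at -1.86, although relative to all genes their direction was lost with MAD scaling within FLAG and within Myc. Amino acid biosynthesis genes fell at 14 of 44 and rose at 1 (median -0.22, adjusted p = 0.0476), with ARG1 at -1.24. Sporulation and meiosis genes rose at 8 of 43 and fell at 5 (median 0.21, adjusted p = 0.0478), with SPS1 at 0.99 and SPS19 at -1.79. Genes within 20 kb of the outermost probe of a chromosome rose at 64 of 208 and fell at 32 (median 0.17, adjusted p = 0.00419), although the members with the smallest p fell (YJR149W and ERG13, -1.33). With an estimated correlation the adjusted p was 0.392 for glycolysis, 0.144 for galactose, 0.346 for amino acids, 0.32 for sporulation and 0.144 for chromosome ends. The glycolysis, galactose and sporulation calls were also lost with normexp and quantile normalization, these 3 and that of amino acids with MAD scaling within FLAG and within Myc, glycolysis with MAD scaling over all arrays, amino acids and sporulation without the GC trend and with the median of probes, and sporulation with 4 or more probes. Adjusted over the list alone, 31 pheromone response, 84 ribosomal protein, 26 respiratory chain, 10 glycolysis, 6 galactose and 14 amino acid genes fell, and 7 sporulation genes and 70 genes near chromosome ends rose. The 6 ioc4 arrays were scanned in a batch of their own, and their FLAG log2 ratios had an SD of 1.11 to 1.26, against 1.32 to 1.43 in WT, so batch and strain cannot be told apart here. Loess within arrays left 508 genes, and MAD scaling within FLAG and within Myc gave 973 rises and 958 falls.

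The mutants were then set against each other. Exchange in isw1 and chd1 differed at 2703 genes (limma), higher in isw1 at 1167 and lower at 1536. It was higher in isw1 at BRE2 (2.29, adjusted p = 2e-13), IRC18 (1.50) and PUL3 (1.55), and lower at ATP2 (-4.02, adjusted p = 1.47e-18), COR1 (-3.13) and the mRNA export factor gene NAB2 (-3.07). Exchange in isw1 and ioc4 differed at 1945 genes, higher in isw1 at 847 and lower at 1098, and here too quantile normalization (1224 higher, 826 lower) and removal of the GC trend (1083 higher, 844 lower) turned the balance. It was higher in isw1 at the weak acid exporter gene PDR12 (2.46, adjusted p = 3.61e-14), YJR096W (2.81) and ALD6 (3.54), and lower at GIT1 (-1.61, adjusted p = 2.33e-11), HXT13 (-1.73) and PFA3 (-2.18). Within scan batch 2 isw1 and chd1 differed at 1218 genes.

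The double mutant differed from the sum of the single mutants at 801 genes, higher at 481 and lower at 320 (limma). It was higher than the sum at VTA1 (2.26, adjusted p = 8.96e-06), the vacuolar zinc transporter gene ZRC1 (1.70) and the proteasome gene RPT3 (1.35), and lower at YNL095C (-1.67, adjusted p = 1.87e-07), SRY1 (-1.15) and DAK2 (-1.36). The count was 22 with loess, 66 with normexp, 164 with MAD scaling over all arrays, 234 with the series matrix and 1351 with FLAG and Myc arrays paired by replicate number within strains. With loess VTA1 (0.92), RPT3 (0.69), YNL095C (-0.74) and SRY1 (-0.51) did not pass, and with normexp YNL095C (-1.2), SRY1 (-0.75) and DAK2 (-0.99) did not. The 3′ shift of the double mutant differed from the sum of the single shifts by -0.08 (permutation p = 0.93). The permutations shuffle labels over all strains of this contrast, whose own shifts widen the null. That p is therefore no evidence that the single shifts add up. The shift was smaller in isw1 than in chd1 by 0.90 (difference -0.90), larger in isw1 chd1 than in isw1 by 1.62 and than in chd1 by 0.72, and larger in chd1 than in ioc4 by 1.57, each with exact permutation p = 0.005 and adjusted p = 0.0075 over 6 comparisons. These p values take FLAG and Myc arrays as independent; with the pairs permuted together no comparison of 2 strains can go below an exact p = 0.1. Between isw1 and ioc4 the difference of 0.67 had p = 0.095 (exact permutation test, adjusted p = 0.114). Every isw1 replicate lay above every ioc4 replicate (-0.21 to -0.10 against -0.82 to -0.79). With FLAG arrays in place, moving Myc arrays, whose means were 0.58 and 0.54, hardly alters the difference. That p therefore says little about whether the strains differ.

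Across genes, changes from WT correlated between chd1 and isw1 chd1 with r = 0.79, and 910 genes rose and 1120 fell in both, against 336 and 496 if the calls were independent. The correlation was 0.51 between isw1 and isw1 chd1, 0.43 between isw1 and ioc4, 0.28 between isw1 and chd1, 0.31 between isw1 chd1 and ioc4 and 0.01 between chd1 and ioc4. All of these share the WT arrays, and simulated changes with no true effect gave 0.50 through that sharing alone; genes are not independent replicates. In covariance the sharing gave 0.017, against 0.43 for chd1 and isw1 chd1, 0.17 for isw1 and isw1 chd1, 0.14 for isw1 chd1 and ioc4, 0.09 for isw1 and ioc4, 0.07 for isw1 and chd1 and 0.0033 for chd1 and ioc4.

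With array medians set to 0, more genes changed in FLAG than in Myc. FLAG enrichment alone rose at 740 genes and fell at 1616 in isw1, rose at 1498 and fell at 1726 in chd1, rose at 1696 and fell at 2090 in isw1 chd1 and rose at 1130 and fell at 1195 in ioc4 (limma). The FLAG balance turned with quantile normalization and with the GC trend removed, to 1050 rises and 856 falls and 1248 rises and 1066 falls in isw1, and to 2082 rises and 1672 falls and 2204 rises and 1664 falls in isw1 chd1. Myc enrichment rose at 1 gene and fell at 2 in isw1, rose at 17 and fell at 111 in chd1, rose at 137 and fell at 101 in isw1 chd1 and rose at 302 and fell at 50 in ioc4. The Myc log ratios spanned less (SD 0.58 to 0.75 per array, against 1.11 to 1.49 for FLAG). The Myc counts, and in every mutant their balance of rises and falls, changed with the scaling; in ioc4, 195 rose and 169 fell with quantile normalization. MAD scaling over all arrays, which gives FLAG and Myc arrays equal spread, gave more Myc than FLAG genes in isw1 (423 and 322) and ioc4 (1532 and 1062), as did the series matrix in ioc4 (1520 and 901), so which tag holds more changes depends on the scaling.

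STE11, FLO8, SPB4 and PCA1, genes known as reporters of transcription from within genes, were followed in each mutant. Exchange over the whole gene fell in isw1 chd1 at the copper and cadmium transporter gene PCA1 (-0.73 ± 0.15 SE, adjusted p = 0.000106 with limma) and at FLO8, a transcription factor gene of invasive growth (-0.49 ± 0.14 SE, adjusted p = 0.00483 with limma). It rose in ioc4 at STE11, a kinase gene of the mating pathway (0.62 ± 0.17 SE, adjusted p = 0.0067 with limma). The FLO8 call was lost with loess (-0.17), with the values of the series matrix (-0.35) and without the GC trend (-0.29), the PCA1 call with loess (-0.34), and the STE11 call with loess (0.42), normexp background correction (0.44) and the median of probes (0.39). SPB4 had values of 0.24 in isw1, -0.20 in chd1, -0.08 in isw1 chd1 and -0.10 in ioc4, none of which passed. Neither did the remaining values, which were -0.33, -0.15 and 0.04 for PCA1 in isw1, chd1 and ioc4, 0.05, -0.33 and -0.36 for FLO8 in those strains, and 0.24, -0.06 and 0.25 for STE11 in isw1, chd1 and isw1 chd1. Some of these passed under alternatives: FLO8 in chd1 with quantile normalization, MAD scaling within FLAG and within Myc, the background filter, the slide as a random block and the replicate block within strains (limma adjusted p = 0.00579), FLO8 in ioc4 with that block (adjusted p = 0.00497), the background filter, 4 or more probes and either slide block, PCA1 in isw1 with that block (adjusted p = 0.0328), MAD scaling over all arrays and the series matrix, PCA1 in ioc4 with MAD scaling within FLAG and within Myc, SPB4 in isw1 without the GC trend, and STE11 in isw1 chd1 with quantile normalization and without the GC trend.

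**Figure D4:**
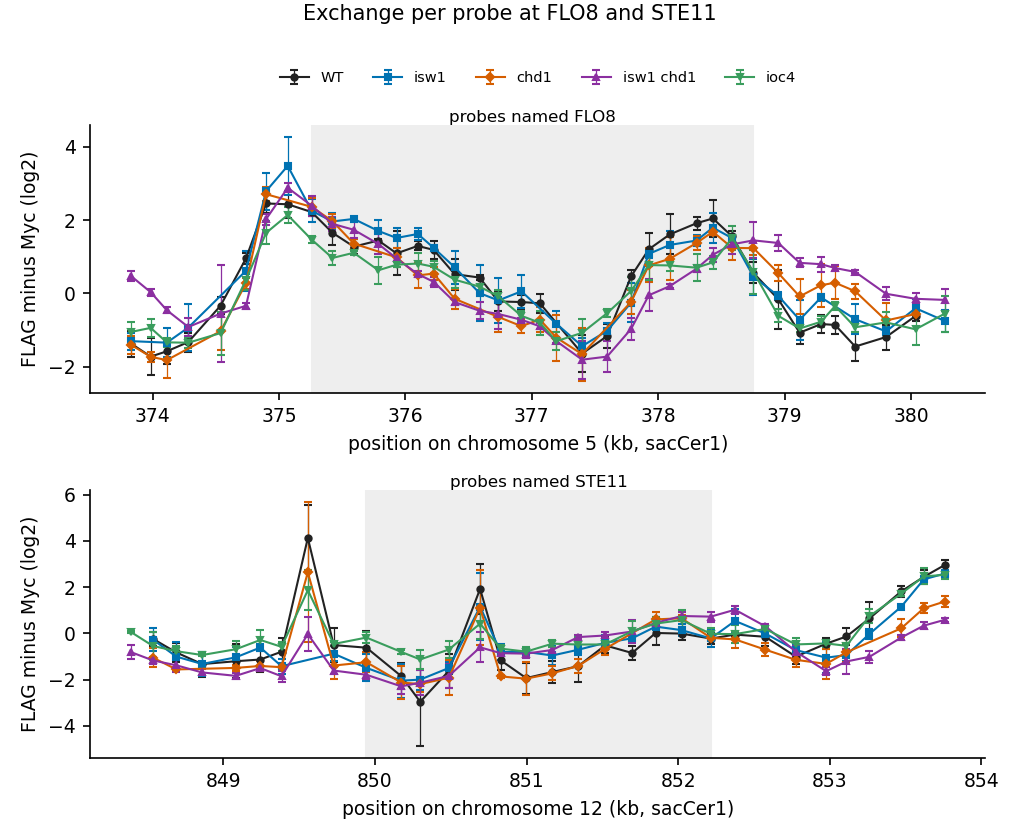
Exchange per probe (FLAG minus Myc enrichment, log2, y axis) along FLO8 on chromosome 5 and STE11 on chromosome 12 (panels; x axis, sacCer1 position in kb), 1 line per strain with the mean and SD of 3 replicates. Averaged over the whole gene, FLO8 went from 0.72 in WT to 0.24 in isw1 chd1 and STE11 from -0.93 in WT to -0.30 in ioc4.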

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

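The counts of other splits, the tests within scan batches, the 2 tests of the ioc4 slide batch and the test of the last part over genes with a convergent neighbour were chosen after the results were seen; the tests of probe GC content, spread of the log ratios and AT-rich probes were chosen before their own results were seen.

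Contrasts between mutants were picked out because the effects of 2 deletions differed in a test of the difference itself. The double mutant differed from the sum of the single mutants at 801 genes, isw1 from ioc4 at 1945 and isw1 from chd1 at 2703. The 3′ shift differed by -0.90 between isw1 and chd1, by 1.62 between isw1 chd1 and isw1, by 0.72 between isw1 chd1 and chd1 and by 1.57 between chd1 and ioc4; these 4 tests take FLAG and Myc arrays as independent, and with the pairs permuted together none can go below an exact p = 0.1. Mitochondrial probes, used in no comparison, were picked out because their centred log2 input in ioc4 differed from WT by -6.30.

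Chance was tested by refitting 100 splits of the 12 arrays of a comparison, the real one included. The real split gave the most genes, 1 of 100, in each of these comparisons, so chance can be excluded for them only if FLAG and Myc arrays vary independently. For exchange the real count and the highest other were 1479 and 1310 in isw1, 2766 and 2528 in chd1, 3271 and 3120 in isw1 chd1 and 1903 and 1534 in ioc4. For the last part they were 1031 and 862 in isw1, 2329 and 2180 in chd1, 2891 and 2712 in isw1 chd1 and 1158 and 824 in ioc4. For isw1 minus ioc4 they were 1945 and 1705, and for isw1 minus chd1 2703 and 2453. The highest other splits left the FLAG arrays in place and moved Myc arrays. Replicate numbers pair FLAG and Myc arrays, and the 10 splits that keep these pairs together are too few for a share under 0.05; among them the highest other count was 0 in each comparison except isw1 minus chd1, where it was 1. For the double mutant against the sum, labels were shuffled over the arrays of all 4 strains, so effects of the single deletions enter these splits. There 4 of 100 splits gave 801 genes or more, under the share of 0.05, although the highest other gave 1394. Such splits do not show what a double mutant equal to the sum would give, so this share decides nothing about chance. With only 10 splits, FLAG or Myc alone cannot give a share under 0.05, and the real split was 1 of 10 as large in each. The real count and the highest other for FLAG were 2356 and 69 in isw1, 3224 and 156 in chd1, 3786 and 0 in isw1 chd1 and 2325 and 5 in ioc4. For Myc the real counts were 3, 128, 238 and 352 in these strains, and the highest other was 0 in each (limma).

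Pattern 1 is the 3′ shift of exchange in isw1, chd1 and isw1 chd1. Probe GC content and the spread of the log ratios each predict a shift near 0 once removed, yet the smallest of the 3 shifts stayed at 0.80 without the GC trend and at 0.88 with equal spread. Promoter probes of a downstream gene, as the source of the rise in the last part, predict no rise over genes with a convergent neighbour. But exchange at the measured promoters fell in isw1 (-0.63), chd1 (-0.98) and isw1 chd1 (-1.62). If downstream promoters fell alike, their probes would lower the last part and could not give a rise. The smallest of the 3 rises over genes with a convergent neighbour, 0.24, therefore adds no support. The shift over these genes had been set as the test but decides nothing, since the fall at the gene's own promoter is part of it. A slide or scan batch as the whole cause is also argued against for isw1 (0.84 within batch 1) and chd1 (1.75 within batch 2). For isw1 chd1 the shift was 2.41 both with and without the slide date as a block. FLAG and Myc arrays of this strain, and those of WT, were spread alike over the dates. Such a block therefore could not alter the shift, and no slide date holds this strain and WT. The only link is a chd1 FLAG array of that slide date. Its last part minus promoter was 0.95, against 1.22 and 1.03 on the chd1 FLAG arrays of batch 2. That is not the direction of the isw1 chd1 shift, but 1 array cannot settle an effect of the slide on FLAG arrays alone. That loss of either remodeler moves H3 exchange from promoters to 3′ ends is therefore a hypothesis for isw1 and chd1, and is open for isw1 chd1.

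Pattern 2 is the change of exchange in ioc4, with falls at ALD6 and ADH2. The FLAG arrays of ioc4 had a narrower spread than those of WT, and with equal spread 1387 of 1903 genes (72.9%) were still called in the same direction. That lies between the bounds set for and against this explanation, so compressed log ratios may account for part of the count. All 6 ioc4 arrays were made on slides of their own scan date, with 0 arrays of another strain, so slide batch and strain cannot be told apart. Loss of Ioc4 stays open as the biological explanation.

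Pattern 3 is the low mitochondrial input in ioc4. The mean over 450 mitochondrial probes was -5.01 in ioc4 and 1.29 in WT, with 0.18 to 2.24 on the 24 arrays of all other strains, and input was at least 54.9-fold lower than in WT since 104 probes did not rise above background. A loss of signal from AT-rich probes is argued against for the 75.8% of mitochondrial probes with enough nuclear probes of like GC content. Those nuclear probes differed by -0.043 between ioc4 and WT. The other mitochondrial probes had too few nuclear counterparts for this comparison. The FLAG IP signal hardly moved: over the mitochondrial probes its centred log2 value was -1.996 to -1.861 in ioc4 and -1.806 to -1.162 in WT. That of Myc (-7.95 to -7.24 and -7.42 to -6.71) lay far below the array median in both strains, so it can show little. The FLAG values speak against cultures without mitochondrial DNA if the FLAG signal there comes from mitochondrial DNA, which was not tested. Since that source is unknown and 0 ioc4 arrays lie outside the batch, loss of mitochondrial DNA in 1 preparation of input cannot be told apart from loss in the strain.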

How the results depend on the processing

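The tests within scan batches, with the slide date as a fixed block, with MAD scaling within FLAG and within Myc, with the GC trend removed and with convergent neighbours were chosen after the data had been seen, and so were the fits of the last part. For signal over background, 98.5% to 99.7% of probes stood well above background, and the minimum of 4 probes, outlier spots and the background filter changed no count by over 1.5 times, but normexp background correction did, for instance from 1479 to 338 exchange genes in isw1. The direction of the 3′ shift held in isw1, chd1 and isw1 chd1 under every alternative run. Its call held too wherever a permutation p was computed, except with FLAG and Myc permuted as pairs, where no smaller p is possible. None was computed with the slide date as a fixed block. Nor was one within scan batches, where isw1 and chd1 have too few arrays for a permutation p under 0.05. The gene counts followed the way the arrays were scaled: among fits on all arrays, loess within arrays gave the lowest exchange count in each mutant and the replicate block within strains, with or without the GC trend, the highest. In the fits within scan batches fewer arrays were tested. With 1 array left in a group, that array is assumed to vary like the others. Where no construction shows it, the cause was not tested. Among values of single genes, lists and segments under alternatives other than left-out arrays, 2755 kept their direction and side of the threshold, 146 lost their call, 28 gained one and 25 turned. The replicate block within strains lost 11 such calls, all of them segment values with an exact permutation p = 0.1. Loess lost 33. The gene list tests and the permutation tests were not run with the slide as a random block, and probes inside 1 open reading frame only and a shorter promoter were not run.

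All counts here are of genes past the threshold with limma, given with their rises and falls where the balance moved by more than 10 percentage points. With array medians at 0 the counts were 3 (1 up, 2 down) in isw1, 128 (17 up, 111 down) in chd1, 238 (137 up, 101 down) in isw1 chd1 and 352 (302 up, 50 down) in ioc4 for Myc, and 8, 5, 5 and 10 lists passed in these strains. With normexp background correction, exchange changed at 338 (133 up, 205 down) in isw1, 1550 in chd1 and 1011 in ioc4, and in the last part at 303 in isw1 and 432 in ioc4. isw1 differed from ioc4 at 1090 (588 up, 502 down), from chd1 at 1523 and the double mutant from the sum at 66 (55 up, 11 down). FLAG enrichment changed at 1190 in isw1, and Myc at 0 (274 at an unadjusted p under 0.05) in isw1, 0 (496 at an unadjusted p under 0.05) in chd1, 12 in isw1 chd1 and 9 (9 up, 0 down) in ioc4. Passing lists numbered 5 in ioc4, the ioc4 shift was 0.13 (permutation p = 0.065) and WT promoter minus gene was 1.2. ISW1 input was -1.74, CHD1 input was -1.74 and IOC4 input was -0.70. With loess within arrays, exchange changed at 73 in isw1, 667 (438 up, 229 down) in chd1, 1654 in isw1 chd1 and 508 in ioc4, and in the last part at 37 (35 up, 2 down) in isw1, 1178 (1124 up, 54 down) in chd1 and 142 (51 up, 91 down) in ioc4. isw1 differed from ioc4 at 656 (373 up, 283 down), from chd1 at 972 and the double mutant from the sum at 22 (20 up, 2 down). FLAG enrichment changed at 578 (260 up, 318 down) in isw1, 1308 in chd1, 2311 in isw1 chd1 and 1144 in ioc4, and Myc at 2 (1 up, 1 down) in isw1, 20 in chd1, 138 (54 up, 84 down) in isw1 chd1 and 129 in ioc4. Passing lists numbered 4 in isw1, 3 in chd1 and 2 in isw1 chd1, STE11 in chd1 turned to 0.041 and SPB4 in isw1 chd1 turned to 0.018. Galactose utilisation in isw1 turned with adjusted p = 0.906, pheromone response in isw1 turned with adjusted p = 0.889 and the ioc4 shift was 0.035 (permutation p = 0.46). The middle part in isw1 changed by -3.98e-05, the last part in ioc4 changed by 0.012 and WT promoter minus gene was 0.84. With MAD scaling over all arrays, exchange changed at 716 in isw1 and 1732 in chd1, and in the last part at 450 in isw1. isw1 differed from chd1 at 1733 and the double mutant from the sum at 164 (120 up, 44 down). FLAG enrichment changed at 322 (149 up, 173 down) in isw1, 1601 in chd1, 2522 in isw1 chd1 and 1062 in ioc4, and Myc at 423 (289 up, 134 down) in isw1, 729 (409 up, 320 down) in chd1, 1456 in isw1 chd1 and 1532 (1040 up, 492 down) in ioc4. Passing lists numbered 5 in isw1 and 3 in chd1, the ioc4 shift was 0.17 (permutation p = 0.39) and the last part in ioc4 changed by 0.041. WT promoter minus gene was 1.80. With quantile normalization, exchange changed at 1044 (641 up, 403 down) in isw1 and 3295 (1827 up, 1468 down) in isw1 chd1, and in the last part at 1153 (1054 up, 99 down) in isw1. isw1 differed from ioc4 at 2050 (1224 up, 826 down). FLAG enrichment changed at 1906 (1050 up, 856 down) in isw1 and 3754 (2082 up, 1672 down) in isw1 chd1, and Myc at 1 (0 up, 1 down) in isw1, 263 (108 up, 155 down) in isw1 chd1 and 364 (195 up, 169 down) in ioc4. Passing lists numbered 5 in ioc4, STE11 in chd1 turned to 0.086 and the ioc4 shift was -0.022 (permutation p = 0.75). The promoter in ioc4 changed by 0.060 and the last part in ioc4 changed by 0.037. With the series matrix values, exchange changed at 759 in isw1, and in the last part at 475 in isw1. The double mutant differed from the sum at 234 (179 up, 55 down). FLAG enrichment changed at 413 (176 up, 237 down) in isw1, 1739 in chd1 and 901 in ioc4, and Myc at 399 (268 up, 131 down) in isw1, 831 (440 up, 391 down) in chd1, 1480 in isw1 chd1 and 1520 (1053 up, 467 down) in ioc4. Passing lists numbered 5 in isw1, PCA1 in ioc4 turned to -0.077 and the ioc4 shift was 0.25 (permutation p = 0.205). The last part in ioc4 changed by 0.0011 and WT promoter minus gene was 1.66. With the replicate block over all arrays, the ioc4 shift was 0.12 (permutation p = 0.0625). With the replicate block within strains, the double mutant differed from the sum at 1351. The isw1 shift was 0.80 (permutation p = 0.1), the chd1 shift was 1.69 (permutation p = 0.1) and the isw1 chd1 shift was 2.41 (permutation p = 0.1). The ioc4 shift was 0.12 (permutation p = 0.1). With only the compared strains, Myc enrichment changed at 0 (373 at an unadjusted p under 0.05) in isw1 and 51 in chd1. With the slide as a random block, Myc enrichment changed at 5 in isw1, 135 in isw1 chd1 and 154 in ioc4. With the median of probes, exchange changed at 886 in isw1. For Myc, the numbers were 0 (284 at an unadjusted p under 0.05) in isw1, 74 in chd1, 70 in isw1 chd1 and 97 in ioc4. SPB4 in isw1 turned to -0.078. With named spans of 2000 bp or more, the middle part in isw1 changed by -0.025, the last part in ioc4 changed by 0.099 and WT promoter minus gene was 1.44. With the first part as reference, the ioc4 shift was 0.066 (permutation p = 0.17).

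Alternatives added after seeing the data gave these values. With scan batch 1 alone, exchange changed at 460 in isw1, and in the last part at 320 in isw1. With scan batch 2 alone, exchange changed at 0 (970 at an unadjusted p under 0.05) in isw1 and 1097 in chd1, and in the last part at 0 (680 at an unadjusted p under 0.05) in isw1. isw1 differed from chd1 at 1218. FLO8 in isw1 turned to -0.019, the isw1 shift was 0.71 and the middle part in isw1 changed by -0.016. With MAD scaling within FLAG and within Myc, exchange changed at 1931 (973 up, 958 down) in ioc4, and in the last part at 1195 (752 up, 443 down) in ioc4. The double mutant differed from the sum at 542 (405 up, 137 down). For Myc, the numbers were 0 (458 at an unadjusted p under 0.05) in isw1 and 72 (19 up, 53 down) in chd1. Passing lists numbered 5 in isw1, 2 in chd1 and 4 in ioc4, STE11 in chd1 turned to 0.081 and the ioc4 shift was 0.071 (permutation p = 0.445). The promoter in ioc4 changed by 0.019, the last part in ioc4 changed by 0.090 and WT promoter minus gene was 1.37. With the GC trend removed, exchange changed at 1382 (796 up, 586 down) in isw1 and 3402 (1972 up, 1430 down) in isw1 chd1, and in the last part at 1357 (1190 up, 167 down) in isw1. isw1 differed from ioc4 at 1927 (1083 up, 844 down). FLAG enrichment changed at 2314 (1248 up, 1066 down) in isw1 and 3868 (2204 up, 1664 down) in isw1 chd1, and Myc at 8 (4 up, 4 down) in isw1, 288 (128 up, 160 down) in isw1 chd1 and 250 (167 up, 83 down) in ioc4. SPB4 in isw1 chd1 turned to 0.064 and the last part in ioc4 changed by 0.044. With the GC trend removed and the replicate block within strains, the last part changed at 1803 in isw1. The double mutant differed from the sum at 1430. SPB4 in isw1 chd1 turned to 0.064, the isw1 shift was 0.80 (permutation p = 0.1) and the chd1 shift was 1.69 (permutation p = 0.1). The isw1 chd1 shift was 2.42 (permutation p = 0.1), the ioc4 shift was 0.14 (permutation p = 0.1) and the last part in ioc4 changed by 0.044. With genes with a convergent downstream neighbour, the last part in ioc4 changed by 0.037.

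Leaving out each array in turn kept every exchange, FLAG, last part and between-mutant count within 1.5 times of its value and every named rise, fall and 3′ shift past its threshold. The Myc counts ranged from 0 to 2 in isw1, from 70 to 124 in chd1, from 98 to 173 in isw1 chd1 and from 122 to 339 in ioc4. In isw1 they were 1 without WT Myc 1, WT Myc 2, isw1 Myc 1 or isw1 Myc 3, and 0 without WT Myc 3 (270 at an unadjusted p under 0.05). In chd1 they were 70 without WT Myc 1, 73 without WT Myc 3 and 71 without chd1 Myc 2. In isw1 chd1 they were 104 and 108 without WT Myc 1 and 3, and 146, 116 and 98 without the double mutant's Myc 1, 2 and 3. In ioc4 they were 216, 146 and 187 without WT Myc 1, 2 and 3 and 122 without ioc4 Myc 2. Values near 0 changed sign: FLO8 in isw1 ranged from -0.023 to 0.17, STE11 in chd1 from -0.22 to 0.065, SPB4 from -0.22 to 0.024 in isw1 chd1 and from -0.24 to 0.0056 in ioc4, PCA1 in ioc4 from -0.042 to 0.14, the middle part in isw1 from -0.0033 to 0.047 and the last part in ioc4 from -0.023 to 0.0069. The isw1 promoter value had a permutation p of 0.05 without WT Myc 2 (-0.60), and the ioc4 promoter value, with 0.04 on all arrays, had 0.055 to 0.085 without any 1 of WT FLAG 3, WT Myc 1, WT Myc 2, ioc4 FLAG 2, ioc4 FLAG 3 and ioc4 Myc 1, 2 or 3. FLO8 passed in chd1 without WT FLAG 1 (-0.38), WT FLAG 2 (-0.40), WT Myc 3 (-0.38), chd1 FLAG 1 (-0.41) or chd1 Myc 3 (-0.40), and in ioc4 without WT FLAG 1 (-0.41), WT FLAG 2 (-0.43), WT Myc 3 (-0.41), ioc4 FLAG 3 (-0.41) or ioc4 Myc 2 (-0.43). PCA1 passed in isw1 without WT FLAG 2 or isw1 FLAG 3 (-0.41 in both), and SPB4 without WT FLAG 1 in chd1 (-0.33) and WT FLAG 2 in isw1 (0.34). Lists near the threshold lost their call: G1/S in isw1 without WT FLAG 1 (adjusted p = 0.0605) or isw1 FLAG 3 (0.0783), chromosome ends in chd1 without chd1 FLAG 3 (0.0552), and amino acids in ioc4 without WT FLAG 2 (0.0546), WT FLAG 3 (0.0629), WT Myc 3 (0.0829), ioc4 FLAG 1 (0.0999) or ioc4 Myc 2 (0.0533). So did sporulation in ioc4 without WT FLAG 1 (0.0826), WT FLAG 3 (0.0629), WT Myc 3 (0.0773), ioc4 FLAG 3 (0.0761), ioc4 Myc 1 (0.0558) or ioc4 Myc 2 (0.061), and spans under 1000 bp in isw1 without WT FLAG 1 (0.0826), WT FLAG 3 (0.0733), isw1 FLAG 1 (0.0765) or isw1 Myc 2 (0.0562).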

Other observations

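The glucose-repressed list, added after the ioc4 values had been seen, was tested only after the result; the comparison of span classes was chosen before its result was seen.

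The histone genes were on the falling side without reaching the list threshold with camera. Exchange fell at 2 of 6 measured histone genes in isw1, 3 in chd1, 4 in isw1 chd1 and 1 in ioc4, and rose at 0 (camera adjusted p = 0.276, 0.182, 0.163 and 0.781). Adjusted over the list alone, 2, 4, 4 and 1 fell. The H3 genes themselves changed most in isw1 chd1, at HHT1 (-2.20) and HHT2 (-2.06). Galactose utilisation genes in isw1 chd1 fell at 5 of 10 and rose at 1 (adjusted p = 0.0741), with GAL2 at -3.05, GAL1 at -2.55 and MTH1, a repressor of hexose transporter genes, at 1.45; in chd1, 5 rose and 3 fell (adjusted p = 0.671). Respiratory chain genes in isw1 chd1 rose at 13 and fell at 11 of 34 (adjusted p = 0.0741), with a median of -0.03 against a mean of 0.35. Sporulation and meiosis genes fell at 21 and rose at 9 of 43 in chd1 (adjusted p = 0.17), with DIT2 at -1.09 and SPO16 at 1.80, and fell at 15 and rose at 8 in isw1 chd1 (adjusted p = 0.578). On the last part alone, camera set these genes below others in chd1 (adjusted p = 5.54e-06) and isw1 chd1 (0.000113). Both calls held with an estimated correlation (adjusted p = 0.0101 and 0.0168). Galactose utilisation genes in isw1 chd1 were also below others there (0.0324), but not with an estimated correlation (0.335). Heat shock genes fell at 8 of 26 in isw1 with 0 rises (adjusted p = 0.069), and 10 fell adjusted over the list alone; they rose at 8 and fell at 8 in isw1 chd1 (adjusted p = 0.867) and rose at 3 and fell at 5 in ioc4 (adjusted p = 0.822).

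The remaining lists did not pass with camera on whole-gene values. On the last part alone, camera set cryptic initiation reporters in chd1 (adjusted p = 0.0434) and chromosome ends in isw1 (0.00783) below other genes. It set M and M/G1 genes in ioc4 (0.0374) and glycolysis genes in chd1 (0.0395) above them. None held with an estimated correlation (adjusted p = 0.166, 0.0844, 0.236 and 0.402). Whole-gene values follow. Among M and M/G1 phase genes 10 of 30 rose and 2 fell in ioc4 (adjusted p = 0.0741), with the daughter cell separation genes DSE4 at 1.08 and DSE1 at 1.06; 4 rose and 4 fell in isw1, 4 rose and 5 fell in chd1 and 7 rose and 9 fell in isw1 chd1 (adjusted p = 0.233, 0.661 and 0.902). G1/S and S phase genes rose at 5 and fell at 11 of 30 in chd1, 5 and 10 in isw1 chd1 and 4 and 5 in ioc4 (adjusted p = 0.233, 0.592 and 0.592). Glycolysis genes rose at 0 and fell at 7 of 21 in isw1, 11 and 4 in chd1 and 4 and 6 in isw1 chd1 (adjusted p = 0.1, 0.231 and 0.468). Ribosome biogenesis genes rose at 3 and fell at 1 of 45 in isw1, 8 and 12 in chd1 and 8 and 3 in ioc4 (adjusted p = 0.289, 0.781 and 0.177). Amino acid biosynthesis genes rose at 1 and fell at 5 of 44 in isw1, 11 and 8 in chd1 and 10 and 11 in isw1 chd1 (adjusted p = 0.982, 0.867 and 0.867). Proteasome genes rose at 11 and fell at 3 of 34 in chd1 and rose at 2 and fell at 10 in ioc4 (adjusted p = 0.125 and 0.361). Cryptic initiation reporters rose at 0 and fell at 1 of 11 in isw1, 0 and 2 in chd1, 2 and 4 in isw1 chd1 and 5 and 1 in ioc4 (adjusted p = 0.472, 0.175, 0.706 and 0.186). Genes near chromosome ends rose at 15 and fell at 42 of 208 in isw1 (adjusted p = 0.891).

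The fry test, here on whole-gene values beside camera, asks whether the genes of a list move 1 way, without comparing them with other genes. It passed lists that camera did not: histone genes in isw1, chd1 and isw1 chd1, glycolysis, heat shock and chromosome ends in isw1, G1/S, proteasome, sporulation and cryptic initiation reporters in chd1, glycolysis, pheromone response, galactose, G1/S, respiratory chain, sporulation and cryptic initiation reporters in isw1 chd1, and M and M/G1, proteasome and cryptic initiation reporters in ioc4. The smallest adjusted p among these was 1.36e-09, for galactose in isw1 chd1, and the largest was 0.0139, for glycolysis in isw1. Of the lists that camera passed, G1/S in isw1 alone did not pass with fry (adjusted p = 0.171).

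Genes with a named span under 1000 bp rose at 83 and fell at 368 of 1586 in isw1 (adjusted p = 0.0434), 324 and 692 in isw1 chd1 (0.0129), 113 and 418 in ioc4 (0.0099) and 315 and 480 in chd1 (0.254), and the calls in isw1, isw1 chd1 and ioc4 were lost with an estimated correlation (adjusted p = 0.32, 0.233 and 0.233). Genes of 3000 bp and over rose at 159 and fell at 86 of 681 in ioc4 (adjusted p = 0.000488, and 0.298 with an estimated correlation) and did not pass in isw1, chd1 and isw1 chd1 (0.884, 0.884 and 0.93). Those of 1000 bp to under 2000 bp (0.341, 0.765, 0.182 and 0.884 in isw1, chd1, isw1 chd1 and ioc4) and of 2000 bp to under 3000 bp (0.359, 0.468, 0.3 and 0.25) did not pass with camera either. On the last part alone, camera set spans of 1000 bp to under 2000 bp below others in chd1 (adjusted p = 0.00402), isw1 chd1 (0.0421) and ioc4 (0.0421). None held with an estimated correlation (adjusted p = 0.138, 0.321 and 0.321). The calls for spans under 1000 bp were also lost with loess in each of the 3 strains, with both MAD scalings and the series matrix in isw1 and ioc4, with 4 or more probes in isw1 and isw1 chd1, with normexp in isw1 chd1 and ioc4 and with quantile normalization in ioc4, and that for 3000 bp and over in ioc4 with normexp, quantile normalization and MAD scaling within FLAG and within Myc. With fry, spans under 1000 bp in chd1, the 3 longer classes in isw1, 3000 bp and over in isw1 chd1 and 1000 bp to under 2000 bp in ioc4 also passed (adjusted p = 0.00387 to 0.0416).

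A hypothesis is that the rise of exchange at 3′ ends in isw1 chd1 depends on the length of the gene. The last part rose at 54.8% of 2140 genes with a named span of 1000 bp to under 2000 bp, at 63.5% of 1057 genes of 2000 bp to under 3000 bp and at 69.7% of 677 genes of 3000 bp and over. The difference of 15.0 percentage points between the outer classes exceeded the 10 set for it, which the hypothesis predicts. With camera, last part changes leaned upward at spans of 3000 bp and over in isw1 chd1 (adjusted p = 0.0454), but not with an estimated correlation (0.452). The same class passed in chd1 (0.0014) and in ioc4 (0.0031), also not with an estimated correlation (0.308 and 0.321). In ioc4 the last part rose at 592 genes and fell at 566, so the trend is not particular to isw1 chd1. Longer spans hold more probes per part and give a more precise mean, which could raise the share and was not separated from length. Precision alone would not raise the median change, which was 0.68, 0.89 and 0.90 in these classes. Falls numbered 353, 145 and 78 in these classes of 2140, 1057 and 677 genes, so their share declined as spans grew longer.

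A second hypothesis is that the falls at ADH2, ALD4, ALD6 and ACS1 in ioc4 belong to a wider fall of exchange at glucose-repressed genes of carbon metabolism. In a list of 25 such genes without those 4, exchange fell at 20 and rose at 0 in ioc4 (median -1.30; camera with an estimated correlation, adjusted p = 0.00701 over the 4 strains), including the gluconeogenesis gene FBP1 (-1.77) and the glyoxylate cycle genes ICL1 (-2.16) and MLS1 (-1.99). Without JEN1 and POT1, whose values had been seen, 18 of 23 fell (median -1.17, adjusted p = 0.0105). The list did not pass in isw1 (0 up, 7 down, adjusted p = 0.389), chd1 (10 up, 8 down, adjusted p = 0.786) or isw1 chd1 (2 up, 15 down, adjusted p = 0.21), although with the preset correlation it passed in isw1 (adjusted p = 0.0337) and isw1 chd1 (adjusted p = 0.000916) as well. Cultures that differ in how far they had used up glucose, a respiratory defect of the strain, or the slide batch of ioc4 could each give such a fall and were not separated. The low mitochondrial input in ioc4 bears on a respiratory defect, but the mitochondrial FLAG IP signal hardly moved, so it settles nothing here.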
